A study of Homo sapiens with 2 samples.

How the data were processed

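MNase-seq was deposited for 2 samples, the breast cancer line MCF7 and the romidepsin-resistant line MCF7 DpVp. Nuclei were digested with micrococcal nuclease and exonuclease III and the released DNA was purified, per the labels' protocols. Bowtie2 and bedtools are named in the submitters' processing notes, without versions, together with the hg19 build. Filters on reads, fragment sizes and duplicates were not given in the sources used here.

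The authors deposited 1 table of 16161 protein-coding genes with 4 columns of read counts, which are whole numbers per gene from its start to its end. A blank cell stands where no read was listed; 6 to 10 genes per column were blank and were taken as 0 reads. The authors also deposited 4 columns of normalised signal. Each equals the count divided by the gene length and by a constant for its column, within 0.48% or less, as tested on the values; the constant is taken to be a read total, which no header states. Reads in genes came to 20.8%, 22.0%, 20.8% and 20.6% of that constant for MCF7 NoRomi, MCF7 Romi, DpVp NoRomi and DpVp Romi. Genes were from 1000 to 199871 bp long, and 2290 of them (14.2%) overlapped another gene of the table. How reads in overlaps were assigned was not given in the sources used here. Starts are given 1-based.

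Columns were assigned by name. Those headed DpVp match the DpVp sample, and those headed Parent were read as the MCF7 sample, which the labels set against the resistant line. The labels name no treatment, so the Romi and NoRomi columns of a line were kept as separate measures of its 1 sample and never averaged. The NoRomi columns were made the main comparison after the headings, but no differences, had been seen. All columns of per-sample values were used (0 left out).

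The design fixed in advance had no test, since there is 1 sample per line. Counts were scaled to equal totals over the genes of the table, as CPM. The log2 ratio was taken on CPM + 1, which understates differences of low genes. Genes past a fold of 2 were counted among those whose mean lay above the lowest 25%. Ratios without pseudocount are printed with exact conditional (Clopper-Pearson) 95% intervals. They cover counting error only, and only where reads are independent molecules. Reads of a library made by PCR may not be, so the intervals can be too narrow. Where a line had no read, the fold was computed against a floor of 3 counts. Gene lists, 15 in all, were fixed before the data were examined. For each, the median log2 ratio has an interval from order statistics, and a percentile among 10000 random lists of equal size matched on mean count in 10 bins. List members outside the table were not analysed here.

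The named genes follow a rule fixed in advance. It takes METTL7A, METTL7B and their listed neighbours, the 10 genes with the largest log2 ratio each way among those past the fold rule, and the highest and lowest member of each list. Other genes were named after their values were seen: the ends of runs, genes past the rule outside runs, list members whose intervals lay on the same side of 1 in both column pairs, and the gene past the rule within MCF7.

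After the data were seen, runs of genes were defined as at least 5 adjacent genes whose running median over 7 genes was at least 1.5-fold in the same direction in both column pairs. Their number was compared with 100 shuffles of the gene order. Gene density was the number of genes of the table within 500 kb. The trend with density was removed by the medians of 20 bins. The spread of single genes was measured around their neighbours at like counts.

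The fold rule was tested on simulated counts, which were Poisson draws from the real means and library sizes of the NoRomi comparison, with 16161 genes. The fold rule called 55 of 55 genes implanted at 3-fold and 56 of 56 at 4-fold. It called 0 of 53 at 1.5-fold and 0 of 11956 unchanged genes. The draws held counting error only. These numbers thus check that the rule runs as set and say nothing of false calls between real libraries. The run finder, on Poisson draws for both column pairs, recovered 20 of 20 genes of 1 run doubled in both pairs. Of 200 random lists, 5.5% fell outside the central 95% of the percentiles. In a separate check of the exact interval, 95.2% of simulated ratios lay inside it. This share checks only that the interval is computed as set. It says nothing of coverage between real libraries.

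Alternatives were counts without scaling, scaling to equal medians, pseudocounts of 0.5 and 5, no filter, and fold thresholds of 1.5 and 3. Those added later were the Romi columns, columns paired across headings (MCF7 NoRomi with DpVp Romi, and MCF7 Romi with DpVp NoRomi), scaling by the constant of the normalised columns, removal of the density trend, genes past the rule in both pairs, and overlapping genes left out. Alternatives planned for profiles or peaks were not run, since the values are per gene. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.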

Results

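MNase-seq, in which micrococcal nuclease digests nuclei and the DNA released is sequenced, was carried out on MCF7 cells and on MCF7 DpVp cells. MCF7 is an estrogen receptor-positive breast cancer cell line, and MCF7 DpVp is a romidepsin-resistant line set against it in the labels. Romidepsin is a histone deacetylase inhibitor that acts through a thiol group, and METTL7A and METTL7B are the methyltransferases named in the title of the study. The labels held 1 sample per line. The deposited values covered 16161 protein-coding genes of the hg19 build, each as reads counted over the whole gene body, exons and introns together. Each line had a column headed NoRomi and a column headed Romi. The headings presumably refer to romidepsin, but the dose and time were not given in the sources used here, and the comparison between lines was made mainly on the NoRomi columns. Reads in genes numbered 12491390 (NoRomi) and 22509140 (Romi) for MCF7, and 9879048 (NoRomi) and 10749389 (Romi) for DpVp. The median gene held 354, 700, 301 and 313 reads in the same order. With 1 library per line and heading, no difference had a replicate check and no p-value was computed. Intervals of ratios of single genes are exact 95% intervals that cover counting error of independent reads only. Those of medians are 95% order-statistic intervals over genes. The latter treat genes as independent, which neighbouring genes are not, and cover no variation between libraries. Counts were not set against a library of undigested DNA, so they follow DNA copy number as well as the release of DNA by the nuclease.

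The comparison at the METTL7 genes addressed whether chromatin over them differed between the resistant and the parental line. METTL7A (chromosome 12, 51318798 to 51326290), a thiol methyltransferase gene, had more reads in DpVp than in MCF7. The counts were 289 in DpVp and 164 in MCF7 in the NoRomi columns, a ratio of 2.23 after scaling to equal totals (95% interval 1.83 to 2.72). The Romi columns held 345 and 284 reads, a ratio of 2.54 (2.17 to 2.99). METTL7A lay at 2.97 and 3.36 times the median gene of the DpVp libraries and at 1.36 and 1.25 times that of the MCF7 libraries, in reads per base. On the log2 scale its difference ranked 62 of 12120 genes in the NoRomi columns and 9 in the Romi columns. The log2 ratio of 1.10 in the NoRomi columns passed the 2-fold rule, but values of 0.78 without scaling, 0.92 with a pseudocount of 5 and, narrowly, 0.999 with equal medians did not. METTL7B (chromosome 12, 56075520 to 56078394), the related methyltransferase gene, had 26 reads in DpVp and 34 in MCF7 in the NoRomi columns, a ratio of 0.967 (0.557 to 1.66). In the Romi columns it had 38 and 82 reads, a ratio of 0.970 (0.642 to 1.44). No difference was detectable at METTL7B at this depth, and its last bases overlap ITGA7.

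Genes on either side of METTL7A differed from each other. The 10 genes before it, from RACGAP1 (starting at 50382945) to TMPRSS12, a serine protease gene, had a median log2 ratio of DpVp to MCF7 of 1.16 in the NoRomi columns and 1.12 in the Romi columns. The 10 genes after it, from HIGD1C to CELA1, had medians of 0.10 and −0.10. METTL7A itself had log2 ratios of 1.10 and 1.28, which differed from the median of the genes before it by −0.06 and 0.16. Single genes scattered around their neighbours with a spread of 0.18 and 0.17 in the same columns. TMPRSS12 (51236709 to 51281663), which ends 37.1 kb before METTL7A, had ratios of 2.51 (2.33 to 2.70) and 3.21 (3.03 to 3.41). HIGD1C (51346327 to 51364483), which starts 20.0 kb after METTL7A, had ratios of 1.14 (0.991 to 1.32) and 0.959 (0.845 to 1.09). METTL7A was the last gene of a run of 17 genes that began at TMBIM6 and covered 1.19 Mb (50135340 to 51326290). The run had median ratios of 2.14 and 1.98, and 13 of its genes passed the 2-fold rule in the NoRomi columns.

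**Figure D1:**
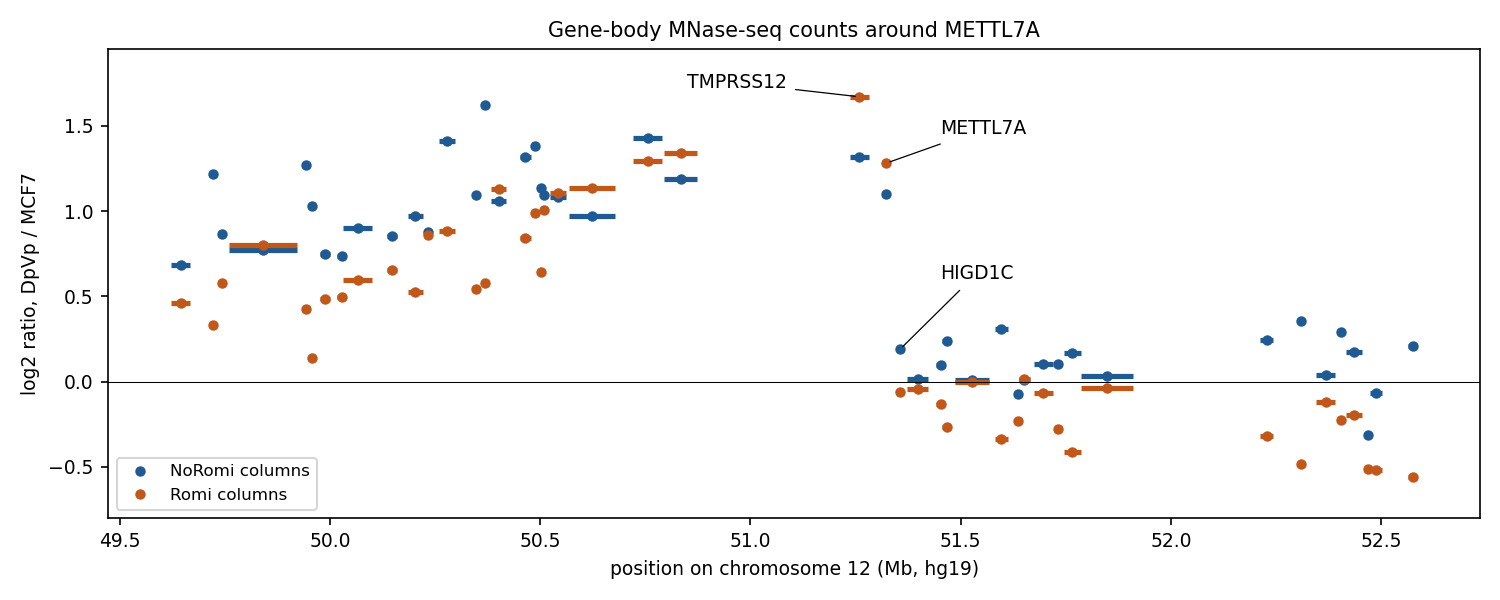
Log2 ratio of DpVp to MCF7 gene-body counts (vertical axis) against position on chromosome 12 in Mb of hg19 (horizontal axis), with bars spanning each gene and dots at gene centres, blue for the NoRomi and orange for the Romi columns. Genes up to METTL7A lie mostly above 0, with METTL7A at 1.10 and 1.28, while the 10 genes after it have medians of 0.10 and −0.10.

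The 12 measured neighbours fixed as a list around METTL7A, all but TMPRSS12 lying after it, had a median log2 ratio of 0.10 (0.02 to 0.24) in the NoRomi columns. It stood at percentile 79.0 of random lists of genes of like mean count and at percentile 56.5 of runs of consecutive genes. In the Romi columns the median was −0.10 (−0.28 to −0.04), at percentile 32.0. Besides TMPRSS12, no member had an interval on the same side of 1 in both column pairs. SLC11A2, an iron transporter gene, had ratios of 1.01 (0.922 to 1.11) and 0.969 (0.895 to 1.05), and DAZAP2 had 0.948 (0.735 to 1.22) and 0.842 (0.675 to 1.04). LETMD1, CSRNP2, TFCP2, POU6F1, BIN2, GALNT6 and SLC4A8 had ratios from 1.01 (TFCP2) to 1.24 (POU6F1) in the NoRomi columns. In the Romi columns they ranged from 0.747 (GALNT6) to 0.996 (TFCP2). The 9 neighbours of METTL7B had medians of 0.12 (−0.08 to 0.36) and −0.03 (−0.18 to 0.11), at percentiles 46.6 and 76.2. Their highest member in the NoRomi columns was BLOC1S1, at 1.40 (0.876 to 2.25) and 0.706 (0.450 to 1.08). The lowest there was RDH5, a retinol dehydrogenase gene, at 0.858 (0.553 to 1.32) and 0.938 (0.672 to 1.30). In the Romi columns BLOC1S1 was the lowest and ORMDL2, at 1.16 (0.856 to 1.57), the highest. None of the 9, which also included ITGA7, CD63, GDF11, SARNP, ORMDL2, DNAJC14 and MMP19, had an interval on the same side of 1 in both column pairs.

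Across the genome, DpVp had more reads than MCF7 by at least 2-fold on the log2(CPM + 1) scale at 117 genes and fewer at 48, of 12120 genes above the filter on low values, in the NoRomi columns. The 10 with the largest positive log2 ratios were TTC34, NFATC1, AQP6, GPC1, CROCC2, KIF1A, CTDP1, BOK, FAM186A and HELZ2. Of these, GPC1, KIF1A and CROCC2 lie in the same run on chromosome 2. NFATC1 and CTDP1 share a run on chromosome 18, and AQP6 and FAM186A lie in the run that ends at METTL7A. NFATC1 (chromosome 18, 77155930 to 77289323), a transcription factor gene of the calcineurin pathway, had a ratio of 3.47 (3.09 to 3.90). KIF1A (chromosome 2, 241653184 to 241760820), which encodes a kinesin motor, had 2.83 (2.59 to 3.09). TTC34 (chromosome 1, 2572708 to 2717433) had 3.75 (3.54 to 3.97), and FAM186A (chromosome 12, 50721092 to 50790392) had 2.70 (2.54 to 2.88). In the Romi columns FAM186A stayed above 2-fold at 2.47 (2.34 to 2.60), while NFATC1 had 1.41 (1.29 to 1.55), KIF1A had 1.38 (1.28 to 1.48), TTC34 had 1.74 (1.66 to 1.83) and HELZ2 had 1.03 (0.893 to 1.19).

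The 10 genes with the most negative log2 ratios were THOC2, XIAP, LRATD2, UPF3B, CUL4B, LAMP2, SLC6A14, DPYS, KIAA1210 and IL13RA1. All but LRATD2 and DPYS lie in a single run on chromosome X, from IL13RA2 to STAG2. LRATD2 lies in the run from HAS2 to MYC on chromosome 8. Genes of the same run are not separate findings. THOC2 (chromosome X, 122734421 to 122866902), an mRNA export gene, had ratios of 0.293 (0.266 to 0.322) and 0.320 (0.293 to 0.348) in the NoRomi and Romi columns. XIAP (chromosome X, 122993558 to 123047822), a caspase inhibitor gene, had 0.299 (0.254 to 0.351) and 0.335 (0.292 to 0.382). UPF3B, a gene of nonsense-mediated mRNA decay, had 0.283 (0.209 to 0.376) and 0.452 (0.360 to 0.563). CUL4B, a ubiquitin ligase scaffold gene, had 0.324 (0.274 to 0.381) and 0.415 (0.360 to 0.478). LRATD2 (chromosome 8, 127564688 to 127570723) had 0.298 (0.246 to 0.360) and 0.360 (0.305 to 0.421). DPYS (chromosome 8, 105391659 to 105479283), the dihydropyrimidinase gene, had 0.356 (0.341 to 0.371) and 0.459 (0.442 to 0.477).

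The genes past 2-fold in the Romi columns numbered 35 higher and 58 lower, and 13 and 24 genes passed in the same direction in both column pairs. Independent lists of these sizes would share 0.338 and 0.230 genes, although both pairs come from the same lines. Of the 117 genes, 103 had the same sign in the Romi columns, as did 48 of the 48. The split between directions depended on the scaling: counts taken without scaling gave 20 higher and 262 lower, and scaling to equal medians gave 61 and 81. It also depended on which columns of the lines were paired, where the ratios of Romi to NoRomi in the lines had a correlation of −0.699 across genes. MCF7 NoRomi paired with DpVp Romi gave 40 higher and 37 lower, and MCF7 Romi paired with DpVp NoRomi gave 43 and 33. Of the 10 genes with the largest positive ratios, 6 and 7 passed the 2-fold rule in these pairings and 1 and 3 stayed among the 10 largest. TTC34 had ratios of 2.05 (1.93 to 2.18) and 3.18 (3.04 to 3.33), KIF1A had 1.99 (1.81 to 2.18) and 1.96 (1.84 to 2.10), and HELZ2 had 1.68 (1.40 to 2.02) and 1.71 (1.51 to 1.93). Of the 10 genes with the most negative ratios, 10 and 9 passed. METTL7A had 2.44 (2.02 to 2.96) and 2.32 (1.96 to 2.74).

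Most genes past the rule in both pairs lay in runs of adjacent genes, a rule chosen after the data were seen. There were 15 runs, 10 higher and 5 lower in DpVp, with 226 genes, and the most found in any of 100 shuffles of the gene order was 0. Shuffling removes any likeness of adjacent genes, so it shows that the ratios follow gene order but not why. The runs held 11 of the 13 and 22 of the 24 genes past the rule in both pairs, which were picked on the same ratios. The genes outside runs, named after their values were seen, were DMRT1 and DMRT3 on chromosome 9, at log2 ratios of 1.37 and 1.18 in the NoRomi columns, and DCSTAMP and DPYS on chromosome 8, at −1.32 and −1.49. On chromosome X, 25 genes from IL13RA2 to STAG2 (114238545 to 123236505), which include XIAP, had median ratios of 0.395 and 0.417. On chromosome 8, 24 genes from HAS2 to MYC (122624356 to 128755197) had median ratios of 0.518 and 0.556. The longest run, 48 genes and 23.7 Mb from TXNL1 to PARD6G on chromosome 18 (54264440 to 78005397), had median ratios of 1.91 and 1.93 and includes BCL2. On chromosome 7, 25 genes from CHRM2 to MRPS33 (136553399 to 140714752) had median ratios of 1.82 and 1.68. On chromosome 2, 22 genes from SH3YL1 to GRHL1 (218136 to 10142405) had 0.612 and 0.570, while 7 genes from NDUFA10 to CROCC2 (240831862 to 241932728) had 2.45 and 1.56. With the columns paired across headings, 19 runs with 311 genes were found, and 199 of the 226 genes lay in runs of the same direction. Inside the runs lay 40 of the 117 genes higher and 33 of the 48 genes lower in the NoRomi columns.

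**Figure D2:**
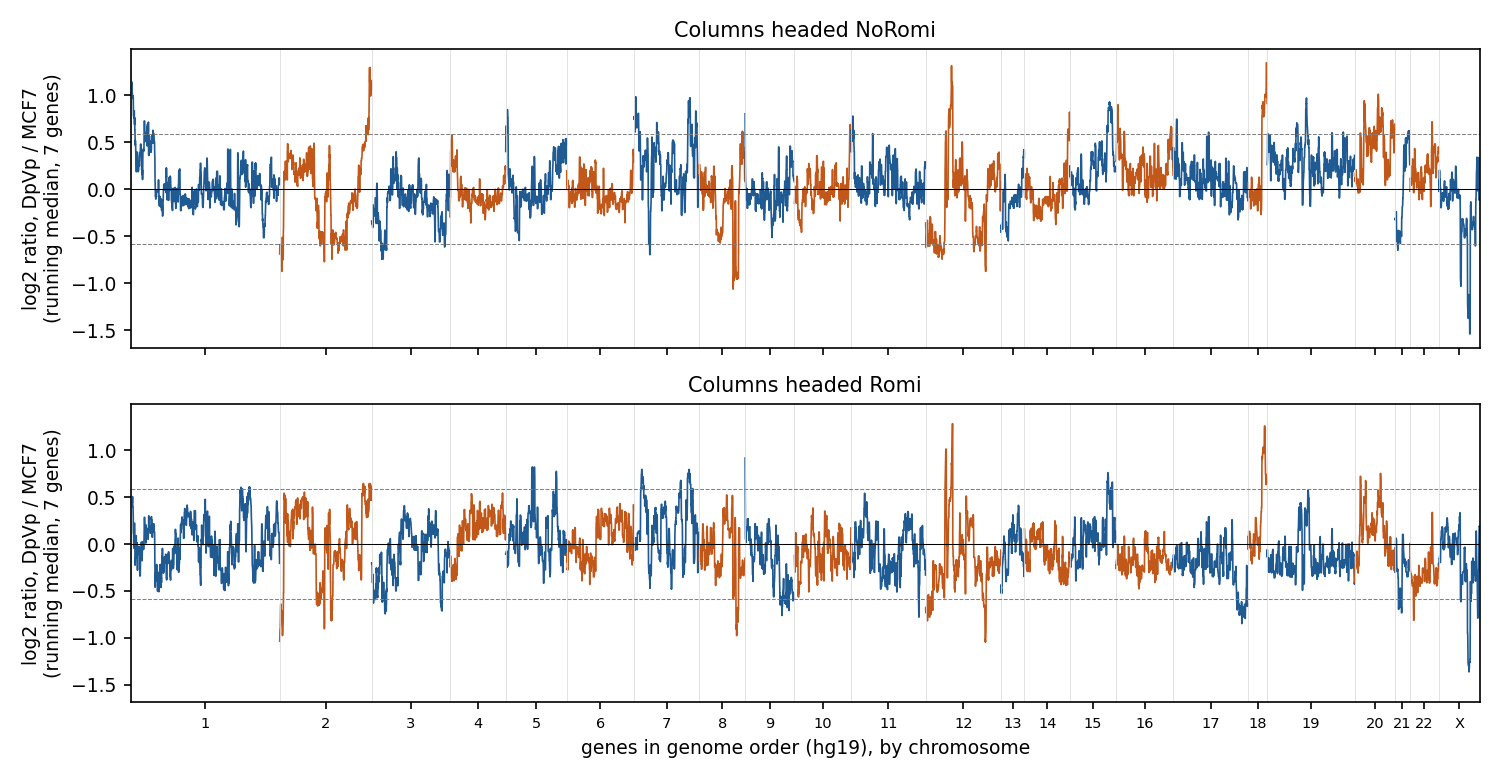
Running median over 7 genes of the log2 ratio of DpVp to MCF7 (vertical axis) for genes in genome order, with chromosomes in alternating colours and the NoRomi columns above the Romi columns; dashed lines mark 1.5-fold. The runs on chromosomes 12 and 18 (higher) and on chromosomes 8 and X (lower) pass the dashed lines in both panels.

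Among the gene lists fixed before the data were examined, the regions of known copy change in MCF-7 held genes at very high counts in both lines. ZNF217 and BCAS1, on chromosome 20, lay at 24.6 and 24.3 times the median gene in MCF7 and at 26.6 and 26.6 times in DpVp, in reads per base of the NoRomi columns. PPM1D and RPS6KB1, on chromosome 17, lay at 15.2 and 15.4 times in MCF7 and at 15.3 and 16.0 times in DpVp. The 9 measured members had median log2 ratios of 0.14 (−0.03 to 0.48) and 0.21 (−0.14 to 0.29), at percentiles 91.2 and 93.7. Intervals lay above 1 in both pairs for 6 members and below 1 for 1, MTAP (chromosome 9, 21802635 to 21867080), at 0.725 (0.606 to 0.865) and 0.676 (0.579 to 0.787). Besides CDKN2A, the 6 were ZNF217, BCAS1 and CYP24A1 on chromosome 20 and PPM1D and RPS6KB1 on chromosome 17. Their ratios were small, from 1.03 (PPM1D) to 1.18 (CYP24A1) in the NoRomi columns and from 1.13 to 1.22 in the Romi columns. Their very high counts make the intervals narrow. The log2 ratio of 0.04 at PPM1D is smaller than the shift of −0.10 from scaling to equal medians. CDKN2A (chromosome 9, 21967751 to 21995323), a cell cycle inhibitor gene lost in many tumours, had no read in either MCF7 column. It had 10 and 16 reads in DpVp, which is 4.21-fold and 11.2-fold higher against a floor of 3 counts in the MCF7 library. In reads per base it was still low in DpVp, at 0.028 and 0.042 times the median gene. The exact 95% intervals, which also cover the counting error in DpVp, start at ratios of 2.83 and 8.08.

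The 10 cell cycle regulators had median log2 ratios of 0.02 (−0.78 to 1.01) and −0.42 (−0.98 to 1.32). These stood at percentiles 22.4 and 0.55, and 2 members had intervals above 1 and 2 below 1 in both pairs. CDKN2B (chromosome 9, 22002902 to 22009312), the inhibitor gene beside CDKN2A, also had no read in MCF7 and had 24 and 21 in DpVp, which is 10.1-fold and 14.7-fold higher against the same floor, with 95% intervals that start at 7.61 and 10.9. In reads per base, CDKN2B lay at 0.29 and 0.24 times the median gene in DpVp. Both inhibitor genes lie above the list median at the start of these intervals too, and the upper ends of both intervals are the value of CDKN2A, which the pseudocount limits. MYC (chromosome 8, 128747680 to 128755197), a growth-promoting transcription factor gene, had ratios of 0.423 (0.363 to 0.492) and 0.413 (0.355 to 0.478). It lay at 5.73 times the median gene in MCF7 and at 2.38 times in DpVp, NoRomi columns. MYC is the last gene of the run on chromosome 8 with median ratios of 0.518 and 0.556.

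The 12 apoptosis regulators had medians of 0.05 (−0.16 to 0.19) and −0.18 (−0.45 to −0.07), at percentiles 33.8 and 25.1. XIAP and BMF had intervals below 1 in both pairs and no member had one above 1. XIAP lies in the run on chromosome X with median ratios of 0.395 and 0.417. The highest member in the NoRomi columns was BCL2L1, an anti-apoptotic gene, at 1.24 (1.14 to 1.34) and 0.949 (0.882 to 1.02). The list of 10 histone deacetylases, which includes the sirtuins SIRT1 and SIRT2, had medians of 0.01 (−0.31 to 0.31) and −0.30 (−0.55 to −0.02), at percentiles 34.2 and 3.27. The ends of both intervals are the values of SIRT1 and SIRT2, and the list was not analysed without these sirtuins. HDAC4, HDAC8 and HDAC9 were listed but are not among the deposited genes. None of the 10 genes had an interval on the same side of 1 in both pairs. HDAC2 (chromosome 6, 114254192 to 114292312) had ratios of 0.796 (0.704 to 0.899) and 1.21 (1.09 to 1.35), and HDAC10 had 1.36 (0.770 to 2.42) and 0.598 (0.345 to 0.995). The 6 measured drug efflux transporters had medians of −0.06 (−0.68 to 0.27) and −0.05 (−0.67 to 0.32), at percentiles 47.3 and 29.2. ABCB1 and ABCC4 were also listed but are not among the deposited genes, so nothing is known of them here. ABCC5 (chromosome 3, 183637724 to 183735672) was the only member with an interval on the same side of 1 in both pairs, at 0.623 (0.576 to 0.673) and 0.627 (0.587 to 0.670). ABCC1, the highest member in the NoRomi columns, had 1.21 (1.15 to 1.28) and 0.807 (0.772 to 0.844).

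The 12 measured genes of the estrogen receptor program had medians of 0.01 (−0.33 to 0.27) and −0.24 (−0.54 to 0.06), at percentiles 46.6 and 5.57. ESR1, XBP1 and AREG were listed but are not among the deposited genes. BCL2 (chromosome 18, 60790579 to 60987002), an anti-apoptotic estrogen target, had ratios of 1.93 (1.78 to 2.09) and 1.70 (1.60 to 1.82). It lies in the run on chromosome 18 with median ratios of 1.91 and 1.93, so its ratios are not particular to BCL2. GREB1 (chromosome 2, 11674171 to 11782914), an estrogen-induced gene, had 0.732 (0.683 to 0.784) and 0.569 (0.537 to 0.603). The 9 luminal genes had medians of 0.07 (−0.32 to 0.31) and −0.11 (−0.54 to 0.39), at percentiles 34.8 and 54.8. FOXA1 lay above 1 and GATA3 below 1 in both pairs, and the members at the ends of the list in the NoRomi columns were MUC1 at 1.34 (1.03 to 1.73) and ELF3 at 0.673 (0.427 to 1.04). In the Romi columns MUC1 had 1.08 (0.838 to 1.38) and ELF3 had 1.17 (0.817 to 1.66). The 8 basal and mesenchymal genes, markers of another breast cell type, had medians of −0.03 (−0.36 to 0.54) and 0.02 (−0.26 to 0.29), at percentiles 22.2 and 76.3. EGFR, a growth factor receptor gene, was the only member with an interval on the same side of 1 in both pairs, at 1.41 (1.33 to 1.5) and 1.22 (1.16 to 1.28). KRT14 had 1.62 (1.02 to 2.57) and 1.07 (0.727 to 1.56), and VIM had 0.768 (0.611 to 0.962) and 0.872 (0.714 to 1.06).

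The other lists had medians whose intervals spanned 0 in both pairs. The 10 genes of insulin and MAPK signalling had medians of 0.11 (−0.84 to 0.38) and −0.11 (−0.39 to 0.12), at percentiles 70.7 and 38.5. Their ends in the NoRomi columns were MAP2K2 at 1.93 (1.69 to 2.21) and 1.09 (0.970 to 1.22), and KRAS at 0.548 (0.482 to 0.622) and 0.931 (0.828 to 1.04). In the Romi columns the ends were IRS1 at 1.38 (1.26 to 1.52) and SPRY2 at 0.517 (0.300 to 0.852). IRS1 had intervals above 1 and DUSP6 below 1 in both pairs. The 11 other thiol and drug metabolism genes had medians of 0.01 (−0.28 to 0.35) and −0.10 (−0.43 to 0.51), at percentiles 34.2 and 48.5. GSTM1 had 1.32 (1.06 to 1.65) and 0.742 (0.608 to 0.901), and TXNRD1, a thioredoxin reductase gene, had 0.670 (0.630 to 0.713) and 0.929 (0.878 to 0.983). The 9 housekeeping genes had medians of 0.06 (−0.40 to 0.68) and 0.02 (−0.18 to 0.36), at percentiles 27.1 and 88.9. GUSB had 1.70 (1.43 to 2.03) and 1.02 (0.886 to 1.16), and GAPDH had 0.632 (0.316 to 1.21) and 0.463 (0.266 to 0.767). TBP was the only member with an interval on the same side of 1 in both pairs, at 1.24 (1.05 to 1.46) and 1.40 (1.21 to 1.61). The 8 genes silent in breast epithelium had medians of 0.27 (−0.43 to 1.04) and −0.21 (−0.52 to 0.20), at percentiles 81.5 and 28.2. MYOD1, a muscle regulator gene, had 3.16 (1.57 to 6.78) and 0.556 (0.276 to 1.04), and NEUROD1 had 0.739 (0.642 to 0.849) and 1.10 (0.973 to 1.24). The list of the 2 METTL7 genes had medians of 0.53 (−0.04 to 1.10) and 0.62 (−0.03 to 1.28), at percentiles 91.8 and 99.7. With 2 genes, these intervals are only the range from METTL7B to METTL7A. The high percentiles come from METTL7A, which is the last gene of a run on chromosome 12. No difference was detectable at METTL7B, so the medians are not a result for both genes.

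Within each line, the Romi and NoRomi columns were compared. In MCF7, gene-rich DNA had relatively more reads in the Romi column, and in DpVp it had relatively fewer. The 12120 genes were put in 5 groups of 2424 by the number of genes within 500 kb. In MCF7 the median log2 ratio of Romi to NoRomi was −0.16 (−0.17 to −0.15) in the group with 0 to 4 neighbours and 0.26 (0.25 to 0.26) in the group with 19 to 58. In DpVp the same groups had medians of 0.08 (0.07 to 0.09) and −0.16 (−0.17 to −0.15). These narrow intervals treat neighbouring genes as independent and cover no variation between libraries. By the 2-fold rule, 1 gene was lower and 0 were higher in the Romi column of MCF7, and 0 genes passed either way in DpVp. The gene was ANGPTL3 (chromosome 1, 63063191 to 63071984), a lipase inhibitor gene, with a ratio of 0.452 (0.364 to 0.560) in MCF7 and 1.21 (0.936 to 1.58) in DpVp. METTL7A had Romi to NoRomi ratios of 0.961 (0.790 to 1.17) in MCF7 and 1.10 (0.936 to 1.29) in DpVp, and METTL7B had 1.34 (0.887 to 2.06) and 1.34 (0.795 to 2.30).

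**Figure D3:**
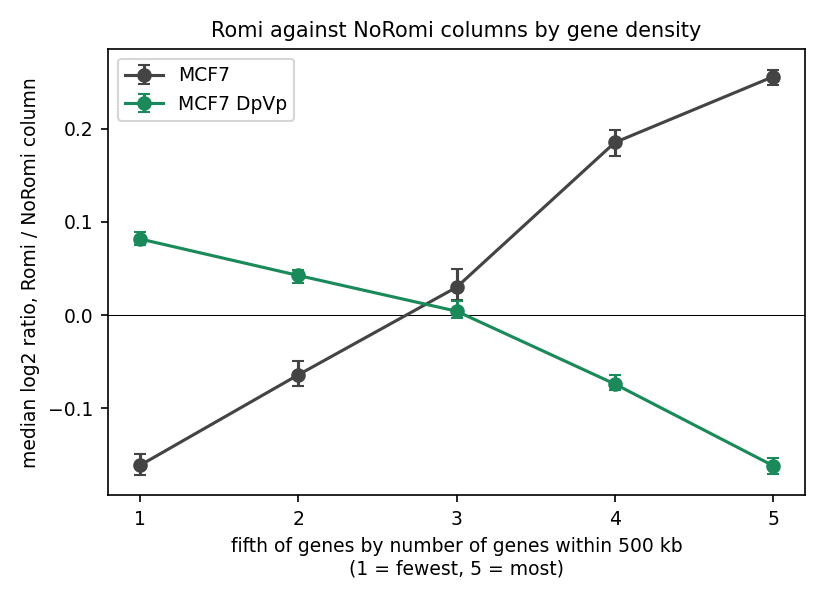
Median log2 ratio of the Romi to the NoRomi column (vertical axis) in 5 equal groups of genes ordered by the number of genes within 500 kb (horizontal axis), in black for MCF7 and green for DpVp, with bars for the 95% order-statistic interval of each median. MCF7 goes from −0.16 to 0.26 and DpVp from 0.08 to −0.16 between the groups with the fewest and the most neighbours. The bars treat genes as independent and cover no variation between libraries.

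Across the 12120 genes, the log2 ratio of Romi to NoRomi in MCF7 and that in DpVp had a Pearson correlation of −0.699 and a Spearman correlation of −0.730, where genes are not independent replicates. The log2 ratios of DpVp to MCF7 in the NoRomi and the Romi columns had correlations of 0.209 and 0.0386. Rank correlations with the number of neighbouring genes were 0.492 for Romi to NoRomi in MCF7 and −0.412 in DpVp. For DpVp to MCF7 they were 0.317 in the NoRomi columns and −0.337 in the Romi columns.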

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

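Of the tests in this part, removal of the density trend (at METTL7A and between the lines) and the size of segments within a line were set before their results were seen; all other tests were chosen after.

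METTL7A had more reads in DpVp, and a change at METTL7A alone is argued against: its log2 ratio exceeded the median of the 10 genes before it by 0.16 at most, under 2 spreads of single genes (0.35). A trend with gene density is argued against as the whole cause, since the ratio without it was still at least 1.03, against 2 spreads of 0.36. More copies of the segment that ends at METTL7A in DpVp may account for the pattern, as a hypothesis. The median steps by at least 1.06 on the log2 scale between METTL7A with the genes before it and the genes after it. This step uses the ratios that also set the end of the run, so it describes the pattern and tests nothing by itself. More nuclease-released DNA over the whole segment at equal copy number cannot be told apart from more copies, since no library of undigested DNA was analysed here. Between the columns of 1 line, running medians of 7 genes reached 0.608 in size in MCF7, past 1.5-fold, and 0.575 in DpVp, under it, while the run that ends at METTL7A had medians of 0.11 and −0.03, which leaves a difference between lines open.

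The Romi and NoRomi columns differed in opposite ways in the lines. The correlation across genes was −0.699, which describes the pattern and tests nothing by itself. Recovery of gene-dense DNA that varied between libraries could account for part of it, but the correlation was still −0.633 with the density trend removed; base composition was not tested. Headings exchanged in 1 line would turn the correlation to 0.699, the sign of a response to Romi shared by the lines. An exchange with a shared response and an opposite response of the lines cannot be told apart with 1 library each.

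CDKN2A and CDKN2B had reads in DpVp that the fold rule left out as low: CDKN2A had 10 and 16 reads and CDKN2B had 24 and 21, in the NoRomi and Romi columns, with none in MCF7. Too few reads in MCF7 is argued against, since 30.3 and 44.0 CDKN2B reads would be due in the MCF7 columns at the DpVp rate. Reads per base at CDKN2B were 10.3 times those at CDKN2A in the NoRomi column (95% interval 4.76 to 24.2) and 5.64 times in the Romi column (2.81 to 11.6), but no library here shows the level of either gene in intact DNA. Admixed DNA with an intact region and a deletion with other ends in DpVp therefore cannot be told apart, and the 21 or more CDKN2B reads in each DpVp column go with either.

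Differences between the lines in the Romi to NoRomi ratio were picked out where the lines went opposite ways; none of these differences was tested. In the density groups the DpVp median less the MCF7 median was 0.24 and 0.11 in the groups with the fewest and next fewest neighbours. It was −0.26 and −0.42 in the groups with the next most and the most. For the neighbours of METTL7A, the DpVp to MCF7 median was lower by 0.20 in the Romi than in the NoRomi columns (−0.20). The median of all genes shifted by −0.14 between the same columns, so much of this difference is not particular to these neighbours.

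Of 64 named genes, 41 had Romi to NoRomi log2 ratios of opposite sign in the lines, lower in DpVp for 28 and higher for 13. For 18 of them the 95% intervals also lay on opposite sides of a ratio of 1, lower in DpVp for 15 and higher for 3, and their values follow. The choice of genes by their NoRomi ratio favours such differences. The DpVp less MCF7 values were −1.10 for TTC34, −1.27 for NFATC1, −1.05 for AQP6, −1.11 for GPC1, −0.76 for CROCC2, −1.03 for KIF1A, −0.84 for CTDP1, −0.82 for BOK and −1.38 for HELZ2. They were −0.65 for POU6F1, −0.58 for ABCC1, −0.38 for BCL2L1, −0.80 for MAP2K2, −0.78 for GSTM1 and −1.57 for MYOD1. The positive values were 0.35 for TMPRSS12, 0.59 for HDAC2 and 0.56 for NEUROD1.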

How the results depend on the processing

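The Romi columns, columns paired across headings, scaling by the constant of the normalised columns, genes past the rule in both pairs, the density trend and overlapping genes were alternatives chosen after seeing the data. METTL7A, with a main value of 1.10 (log2), was higher in DpVp under each alternative of scaling, pseudocount and column pairing, from 0.78 without scaling to 1.28 in the Romi columns. With the density trend removed it had 1.03 in the NoRomi and 1.39 in the Romi columns. It was under the 2-fold rule without scaling, with a pseudocount of 5 (0.92) and with equal medians (0.999). Without scaling, the median of all genes shifts by −0.32, and in the Romi columns by −0.14, so values under these are to be read against those shifts. Without scaling, 20 genes were higher and 262 lower by the fold rule (7.09% higher, against 70.9% in the main comparison), as set by the unequal totals. Equal medians gave 61 and 81 (43.0%), a pseudocount of 5 gave 54 and 31, no filter gave 219 higher, and folds of 1.5 and 3 gave 897 and 417, and 3 and 4. The Romi columns gave 35 higher (37.6%) and both pairs together gave 13 and 24, of which the cause was not tested. With the headings of DpVp exchanged 40 genes were higher (51.9%), and with those of MCF7 exchanged 43 (56.6%), of which 34 and 28 are among the 117 of the main comparison.

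List medians without scaling were −0.23 for the METTL7A neighbours (reversed), −0.16 for the METTL7B neighbours, −0.32 for histone deacetylases, −0.37 for basal genes, −0.27 for apoptosis regulators, −0.31 for other thiol genes and −0.20 for regions of known copy change. The METTL7A neighbours had 0.00043 with equal medians and −0.10 (reversed) in the Romi columns, and apoptosis regulators had −0.18 there; with the MCF7 headings exchanged these lists had −0.089 (reversed) and −0.19. The cause was not tested. Of 65 log2 ratios of named genes, 54 lay within their counting interval of the main value with equal medians and 21 in the Romi columns. Windows at transcription start sites, smoothing of profiles and peak overlaps were not run, since the values are per gene. Depth limits small genes: the interval at METTL7B, with 26 and 34 reads, spans 0.557 to 1.66.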

Other observations

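All values in this part were picked after the data were seen. Whole chromosomes differed in their median log2 ratio of DpVp to MCF7. The median of all genes, with those under the filter, was 0.06 in the NoRomi and −0.08 in the Romi columns. Chromosome 20 had 0.46 in the NoRomi and 0.12 in the Romi columns over 363 genes, and chromosome 7 had 0.26 and 0.18 over 586. Chromosome 12 had −0.15 and −0.23 over 677 genes, although it holds the METTL7A run. Chromosome 3 had −0.15 and −0.09 over 704, where the Romi value lies near the median of all genes. Chromosomes 19 and 22, which are rich in genes, had medians of opposite sign in the column pairs, 0.26 and −0.18, and 0.18 and −0.34.

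Smaller runs were also present in both pairs. On chromosome 12, 10 genes from IFT81 to TCTN1 had median ratios of 0.559 and 0.505, and 5 genes from ZCRB1 to IRAK4, a kinase gene of innate immune signalling, had 1.55 and 2.02. On chromosome 15, 13 genes from SAXO2 to ZSCAN2 had 1.65 and 1.60, and 5 genes from NGRN to BLM, a DNA helicase gene, had 1.63 and 1.60. On chromosome 20, runs of 6, 5 and 7 genes had NoRomi medians of 1.51, 1.56 and 1.53, and on chromosome 3, 7 genes from CMTM7 to CRTAP had 0.666 and 0.653. Among cell cycle and MAPK genes on chromosome 12, CDKN1B had ratios of 0.518 and 0.412, and DUSP6, a MAPK phosphatase gene, had 0.514 and 0.736.

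Across genes, log2 levels of MCF7 NoRomi correlated at 0.890 with MCF7 Romi, at 0.890 with DpVp Romi and at 0.821 with DpVp NoRomi. Those of MCF7 Romi correlated at 0.870 with DpVp NoRomi and at 0.831 with DpVp Romi, and the DpVp columns correlated at 0.944 with each other. Libraries under opposite headings were thus closer across lines than those under the same heading.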
